A study of Drosophila melanogaster with 6 samples.

How the data were processed

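The series holds 6 libraries of chromatin from 0 to 16 h embryos: E(Z), H3K27me3 and input from the line overexpressing the forward RNA and the same from the line overexpressing the reverse RNA. Groups were taken from the sample titles. Per the labels' protocols, homozygous transgenic flies were crossed to homozygous daughterless GAL4 flies, crosslinked chromatin was sonicated and immunoprecipitated, and libraries were made with an Illumina-type kit. Per the submitters' processing notes, reads were handled with Bowtie 0.12.5 and the builds named were dm3 and BDGP5.

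The authors deposited 2 read lists per library, 12 in all, with 1 row per aligned read of 50 bp: one list on the genome (dm3, 15 sequences) and one on a single reference sequence for the transgene. The score column of the deposited lists is 255 in every row and carries no information, and start, end and strand are the only values used. Filters applied by the authors to multiply aligned reads are not given in the sources used here.

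Reads on the arms 2L, 2R, 3L, 3R, 4 and X were counted by their 5' end moved 55 bp towards the fragment centre. The strand cross-correlation was highest at the read length in all 6 libraries and showed no separate fragment peak, so the fragment length of 110 bp, taken from the highest value at longer distances, is uncertain. All reads were kept. H3K27me3 domains were called on the sum of both lines in bins of 1 kb with at least 10 pooled input reads, an IP over input ratio of at least 2 (each per arm reads) and an upper-tail Poisson probability with a Benjamini-Hochberg adjusted value under 0.001. That probability only calls regions against input and does not compare the lines. Bins up to 2 kb apart were merged and domains of at least 5 kb kept. E(Z) regions were called likewise in bins of 500 bp, merged up to 500 bp apart, with at least 1 kb.

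The value compared is the log2 of reverse over forward IP over input. Its interval comes from the Poisson error of the 4 counts, a single IP over input ratio has an exact conditional binomial interval, and shares have exact Clopper-Pearson intervals. Reads carry no molecular identifiers, so all intervals at 95% cover counting error only, and regions are not replicates. No probability across regions is given. With 1 library per group, leaving out a replicate or pairing samples was not possible.

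The layout of the transgene was derived from reads present by name in both lists of a library. Of the transgene reads, 86.4% to 90.5% were also in the genome list. The vector was counted in bins of 100 bp between the left flank and the PRE, and 2 of the 32 bins, whose input density was above that of the left flank, were left out. That filter was chosen after the data were seen.

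Regions named in the text followed a rule fixed before the data were examined: the vg locus and the transgene, the 10 domains and 10 E(Z) regions with the highest and the 10 with the lowest reverse over forward ratio among those with at least 50 reads in each of the 4 libraries, and the 10 longest domains. Lists of Hox, segmentation, wing, eye and neural, mesoderm and Polycomb group genes, and control lists, were also fixed. They were not run, because the gene table used here is of Release 6 plus ISO1 MT, another build than the files, and coordinates were not converted. For the same reason the vg gene body was replaced by the domain and the E(Z) region that hold the PRE, and regions are given by position. In that table vg is a protein-coding gene on 2R.

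The calling and ratio steps were tested on simulated data with 200 regions drawn on the input libraries' own profile. At a simulated 2.5-fold enrichment 100.0% of H3K27me3-like and 99.0% of E(Z)-like regions were called. At 2.0-fold, the level at which the threshold lies, 61.5% and 50.5% were called, so many regions near this level are missed. The simulated log2 ratio lay inside 93.5% to 96.5% of the intervals, and 0 false regions were called. All simulated libraries, input included, were Poisson counts from 1 shared input profile. They hold no scatter beyond counting error, so these results do not measure false calls or interval coverage in the real libraries. Alternatives covered repeated reads, the calling ratio, scaling, use of input, depth, bin size, which line defines the regions, the shift, domain length and the PRE fragment. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.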

Results

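Chromatin of whole Drosophila melanogaster embryos, collected from 0 to 16 h, was profiled by chromatin immunoprecipitation and sequencing in 2 transgenic lines. Each line carried the Polycomb/Trithorax response element (PRE) of vestigial (vg), a regulator of wing development, at the same ectopic site. Crossing to flies with GAL4 driven by daughterless, a broadly expressed gene, made the embryos overexpress the noncoding RNA of the PRE in the forward direction in one line and in the reverse direction in the other. Antibodies were directed against E(Z), the enzyme of the Polycomb system that methylates lysine 27 of histone H3, and against its product H3K27me3, and input chromatin was sequenced for each line. The question set by the design was how the strand of the overexpressed RNA bears on E(Z) binding and H3K27me3. There was 1 library per line and antibody, so no difference between the lines has a replicate check, no test against replicates was possible, and every interval below is a 95% interval that covers counting error alone.

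The genome files held between 9166406 reads (E(Z), reverse line) and 16023176 reads (input, forward line). The 6 chromosome arms 2L, 2R, 3L, 3R, 4 and X held 14038806 reads of E(Z) in the forward line and 8853047 in the reverse line. H3K27me3 had 8856427 arm reads in the forward line and 9409385 in the reverse line, and input had 15259199 and 11281967. Reads at a position and strand already taken by another read of the library made up 19.6% of the arm reads of H3K27me3 in the reverse line and 4.84% in the forward line. The corresponding shares were 9.84% and 7.89% for E(Z) in the forward and reverse line, and 5.02% and 5.05% for input. The transgene files held between 4172 and 7222 reads.

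H3K27me3 lay in 136 domains on the summed lines, and its enrichment there was higher in the reverse line. The domains covered 1.72 Mb, or 1.43% of the arms, with a median length of 9 kb. They held 2.97% of the H3K27me3 reads against 1.46% of the input reads in the forward line, an enrichment of 2.04-fold (2.03 to 2.05). In the reverse line they held 3.21% against 1.39%, an enrichment of 2.31-fold (2.30 to 2.33). Domains were called on these same reads, so the level of enrichment follows the calling ratio. In the forward and reverse line it was 1.71 and 1.90 at a calling ratio of 1.5, and 3.06 and 3.75 at 3. 3R held 37 domains, 3L and X held 28 each, 2R held 23 and 2L held 20, while chromosome 4 held 0.

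The IP over input ratio was higher in the reverse line in 134 of the 136 domains. The median reverse over forward ratio was 1.14-fold, or 0.19 on the log2 scale, with 0.03 to 0.33 as the range from the 5th to the 95th percentile of domains. The counting interval lay above 0 in 87 domains, below 0 in 0 and spanned 0 in 49. Over 1000 windows drawn outside the domains the median log2 ratio was -0.01. Scaling to arm reads, few of which lay in domains, holds this value near 0, so it is no separate reference. Domains differed little from each other: the interval lay above the median of all domains in 1 domain and below it in 5, where counting error alone would put 3.4 on each side. Leaving out the input division lowered the median log2 ratio to 0.12.

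The longest domain, 66 kb at X 5,440,001 to 5,506,000 on dm3, had an IP over input ratio of 2.04 in the forward line and 2.31 in the reverse line. The next in length, 52 kb at 3R 17,253,001 to 17,305,000, had 2.25 and 2.57. Of the 10 longest domains, 9 had a counting interval of the reverse over forward ratio above 1, and their log2 ratios ran from 0.06 to 0.24. Among the 10 domains with the highest log2 ratio, between 0.32 and 0.44, were X 4,372,001 to 4,378,000 (1.82 in the forward and 2.48 in the reverse line) and 2R 10,089,001 to 10,094,000 (1.94 and 2.61). The 10 lowest ran from -0.05 to 0.04, and 4 of them were on X. The lowest, X 9,584,001 to 9,593,000, had 2.27 in the forward line and 2.19 in the reverse line. None of those 10 had an interval above 1, which choosing the lowest favours. The domains scattered about as counting error allows, so these ranks do not show that single domains differ.

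**Figure D1:**
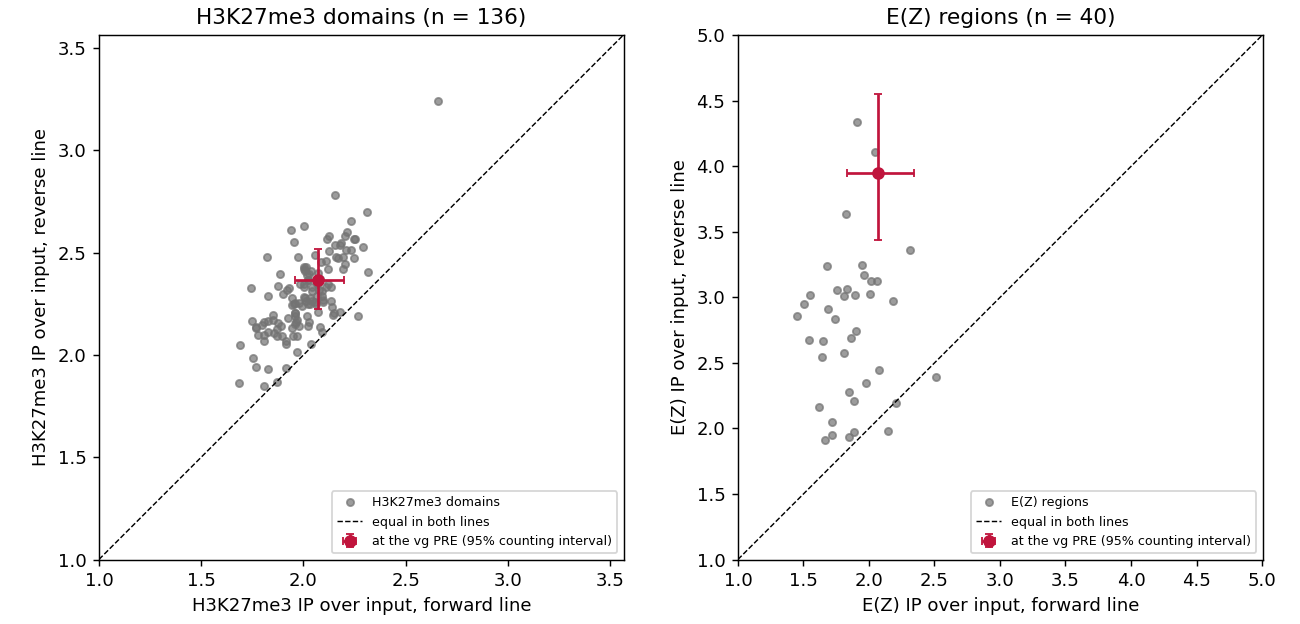
IP over input (ratio, linear axes) in the forward line against the reverse line, for the 136 H3K27me3 domains (left) and the 40 E(Z) regions (right), with 1 point per region, the region at the vg PRE in red with its 95% counting intervals and equality as the dashed line. Of the H3K27me3 domains 134 lie above the line, and of the E(Z) regions 37 do.

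E(Z) was enriched over input in 40 short regions on the summed lines, which held a small part of its reads, and there too the enrichment was higher in the reverse line. The regions covered 50.5 kb in total, and 19 of them overlapped one of the 136 H3K27me3 domains. With domains called at an IP over input of 1.5, which cover 5.10% of the arms, 32 overlapped. Regions held 0.0831% of the E(Z) reads against 0.0455% of the input reads in the forward line, an enrichment of 1.83-fold (1.77 to 1.88). In the reverse line the enrichment was 2.88-fold (2.79 to 2.98). These levels also follow the calling ratio, and at 1.5 they were 1.53 in the forward and 1.90 in the reverse line.

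The E(Z) ratio was higher in the reverse line in 37 of the 40 regions, with a median of 1.53-fold, or 0.62 on the log2 scale (-0.01 to 0.997 from the 5th to the 95th percentile). The interval lay above 0 in 27 regions and below 0 in 0. The median of 1000 windows outside the regions was -0.01, which the scaling to arm reads likewise holds near 0. The size of this difference depended on how regions were chosen. It was 0.23 over the 898 regions called at a ratio of 1.5, and it was -0.39 over the 21 regions called on the forward line alone, which picks bins that were high in that line.

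The 32 regions inside H3K27me3 domains called at 1.5 and the 8 outside, a split made after the data were seen, had unlike ratios. Inside, the median IP over input was 1.84 in the forward line and 2.99 in the reverse line, a log2 ratio of 0.69, and all 32 were higher in the reverse line. Outside, the medians were 1.98 and 2.12, the log2 ratio was 0.12, and 0 of the 8 had an interval above 0. The regions outside were thinly covered, with a median of 79 input reads over both lines against 332 inside. They were not low in H3K27me3, whose median IP over input was 2.10 in the forward line and 2.39 in the reverse line outside, against 1.82 and 1.97 inside. That ratio divides by the same thin input counts as the E(Z) ratio, so it is no separate evidence of marking. The difference between both sets was not tested.

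The highest reverse over forward ratio among the 34 E(Z) regions with at least 50 reads in each library was at X 8,544,501 to 8,545,500, where IP over input was 1.91 in the forward line and 4.34 in the reverse line (log2 ratio 1.18). The regions at 3R 2,718,501 to 2,719,500 (2.04 and 4.11) and X 17,662,001 to 17,663,500 (1.82 and 3.63) followed. The region at the vg PRE was also among the 10 highest, whose log2 ratios ran from 0.79 to 1.18. The 10 lowest ran from 0.06 to 0.53, and 3 of those had an interval above 1. The lowest were 3L 1,750,001 to 1,752,000 (1.89 and 1.97) and 2L 9,552,001 to 9,553,500 (1.84 and 1.94).

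Across whole H3K27me3 domains E(Z) was less enriched than in its own regions, with a median IP over input of 1.12 in the forward line and 1.34 in the reverse line. It was higher in the reverse line in 134 of the 136 domains, by a median log2 ratio of 0.25. H3K27me3 over the 40 E(Z) regions was higher in the reverse line in 33. Over domains, which are not independent replicates, the Spearman rho of the E(Z) change with the H3K27me3 change was 0.16. The H3K27me3 changes scattered among domains no more than counting error allows (chi-square over degrees of freedom 1.01). The rho could thus hardly show a relation, and none is read from it. Both changes share the input libraries. With input left out of H3K27me3 the rho was -0.20, with input left out of E(Z) it was -0.38, and with input left out of both it was 0.044.

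At the endogenous vg locus the H3K27me3 domain that holds the PRE had a reverse over forward ratio close to the median domain. That of E(Z) lay above the median E(Z) region in the 3 windows at or next to the PRE given below, beyond counting error in 1. In wider windows the E(Z) log2 ratio relative to the median region was -0.12 over the domain and -0.28 in the 5 kb before and after the fragment. The PRE fragment of the transgene matched 2R 8,792,046 to 8,793,633 on dm3, found from reads that were aligned both to the transgene and to the genome. The vg gene body was not placed on this build, so whether the fragment is exonic or intronic is not given here. The H3K27me3 domain around it, 2R 8,784,001 to 8,798,000, had an IP over input of 2.07 (1.96 to 2.20) in the forward line and 2.37 (2.22 to 2.52) in the reverse line. Its log2 ratio of 0.19 (0.07 to 0.31) ranked 63 of 136. On the PRE fragment alone H3K27me3 was 1.93 (1.68 to 2.21) in the forward line and 2.47 (2.14 to 2.84) in the reverse line, a log2 ratio of 0.36 (0.08 to 0.63), which lay 0.17 (-0.11 to 0.44) above the median domain. Over the E(Z) region at the PRE it was 1.92 and 2.56, a log2 ratio of 0.41 (0.13 to 0.70), which lay 0.23 (-0.06 to 0.51) above the median domain. Neither excess was distinguishable from 0 by counting error. The neighbouring domains at 2R 8,772,001 to 8,781,000 and 8,836,001 to 8,845,000 had log2 ratios of 0.13 (-0.02 to 0.29) and 0.10 (-0.04 to 0.25).

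The E(Z) region at the PRE, 2R 8,792,001 to 8,793,500, had an IP over input of 2.07 (1.83 to 2.35) in the forward line and 3.95 (3.44 to 4.55) in the reverse line. Its log2 ratio was 0.93 (0.67 to 1.20), which ranked 8 of 40 and lay 0.32 (0.05 to 0.58) above the median region. The interval of the log2 ratio includes 0.69, the median of the 32 regions inside H3K27me3 domains called at 1.5. An excess beyond counting error thus depends on counting the 8 thinly covered regions outside in the median. On the PRE fragment the E(Z) log2 ratio was 0.84 (0.58 to 1.09), and its excess of 0.22 (-0.04 to 0.48) over the median region was not distinguishable from 0. The excess of the called region was 0.18 (0.04 to 0.32) without input and 0.55 (0.23 to 0.87) with all libraries thinned to the shallowest. On the scale of the excess over input, 1 factor fitted to all 40 regions, vg included, put vg at 3.52 in the reverse line. That was 1.04 standard deviations of counting error below the measured value, so that vg did not stand apart on that scale. Because vg was part of the fit, its deviation is biased towards 0. Reads on the fragment come from the endogenous and the transgenic copy alike and cannot be separated. Input density over the fragment was 1.87 (1.67 to 2.09) times that of the 5 kb on each side in the forward line and 1.92 (1.68 to 2.19) times in the reverse line. In the 1 kb on each side of the fragment, which the transgene does not carry, E(Z) was 1.16 in the forward line and 1.90 in the reverse line. The log2 ratio there was 0.72 (0.38 to 1.06), which lay 0.10 (-0.24 to 0.44) above the median region and so was not distinguishable from it. H3K27me3 over the same flanks was 2.18 and 2.19.

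**Figure D2:**
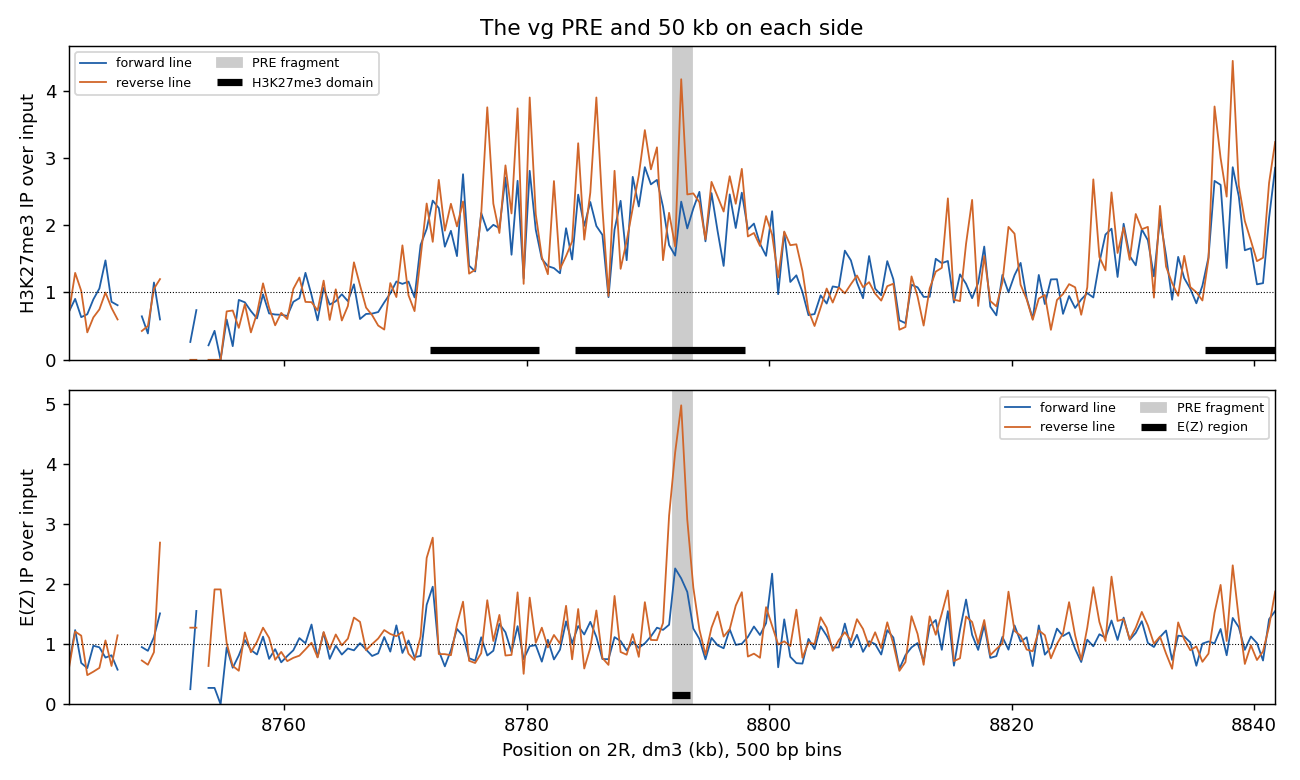
IP over input (ratio) in 500 bp bins along 2R (dm3, kb) around the PRE fragment (grey), with H3K27me3 above and E(Z) below, 1 curve per line and black bars for called domains and regions. Gaps are bins without input reads. The E(Z) curve peaks at the PRE in both lines, where the called region had 2.07 in the forward line and 3.95 in the reverse line.

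On the transgene, E(Z) and H3K27me3 extended from the PRE into the adjoining vector sequence, where E(Z) was higher and H3K27me3 not higher in the reverse line. On the PRE part of the construct, whose reads are shared with the endogenous copy, both were higher in the reverse line: E(Z) was 2.10 in the forward line and 3.75 in the reverse line, and H3K27me3 was 1.98 and 2.5, a log2 ratio of 0.34 (0.06 to 0.62). The transgene references of 38,418 bp held flanks of the insertion site at 2R 5,965,082 to 5,965,085, vector sequence, the PRE in opposite orientations in the 2 lines, and 2 parts that also aligned to X. Input density over the vector was 0.470 (0.408 to 0.540) of that over the left flank in the forward line and 0.488 (0.418 to 0.567) in the reverse line. Over 3000 bp of vector between the left flank and the PRE, E(Z) IP over input was 1.37 (1.15 to 1.64) in the forward line and 2.03 (1.69 to 2.44) in the reverse line, a log2 ratio of 0.56 (0.20 to 0.92). H3K27me3 was 1.80 (1.49 to 2.16) in the forward line and 1.44 (1.19 to 1.75) in the reverse line, a log2 ratio of -0.32 (-0.69 to 0.06). In vector bins with no read that aligned to dm3, a choice made after the data were seen, the log2 ratio was 0.27 (-0.21 to 0.75) for E(Z) and -0.65 (-1.17 to -0.13) for H3K27me3.

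In the last 1000 bp before the PRE, E(Z) was 1.56 (1.16 to 2.11) in the forward line and 2.99 (2.20 to 4.12) in the reverse line. H3K27me3 was 2.36 (1.75 to 3.21) and 1.88 (1.34 to 2.64). The E(Z) log2 ratio there was 0.94 (0.34 to 1.54). In the vector farther from the PRE, positions 10,101 to 12,000, it was 0.28 (-0.22 to 0.78), not distinguishable from 0. For H3K27me3 in that part it was -0.16 (-0.69 to 0.37). The flanks were near the input level: over the left flank H3K27me3 was 0.926 and 0.928 and E(Z) 0.970 and 0.937 in the forward and reverse line, and over the right flank H3K27me3 was 0.885 and 0.95 and E(Z) 1.03 and 1.11. Reads on the flanks and on the X-linked parts come also from chromosomes without the insertion and from the endogenous X copies, which dilutes any signal of the transgene there. On the first X-linked part, on the other side of the PRE from the vector, H3K27me3 was 0.944 and 1.05 and E(Z) 1.04 and 1.02 in the forward and reverse line. On the second, H3K27me3 was 0.931 and 0.826, a log2 ratio of -0.17 (-0.34 to -0.01), and E(Z) was 0.899 and 0.838. The 50 kb on each side of the insertion site had H3K27me3 at 0.879 in the forward line and 0.859 in the reverse line.

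**Figure D3:**
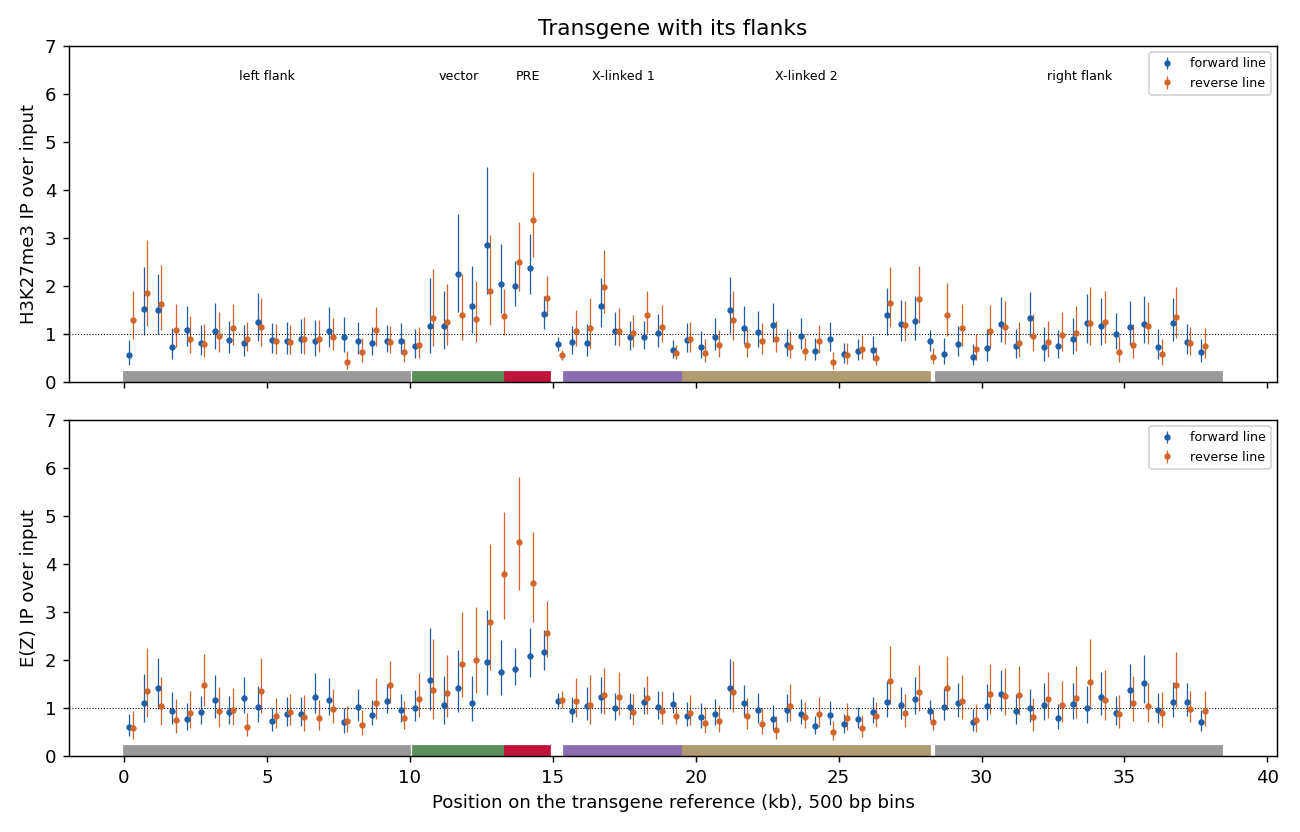
IP over input (ratio) in 500 bp bins along the transgene reference (kb), with H3K27me3 above and E(Z) below, 1 point per bin and line with 95% counting intervals, and the parts of the construct marked along the axis. Over the vector E(Z) was 1.37 in the forward line and 2.03 in the reverse line, and the 4 values over the whole left flank lay between 0.926 and 0.970, with single bins scattered more widely.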

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

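The tests of PRE orientation, of E(Z) against windows inside domains and of H3K27me3 against windows outside were chosen after the results they bear on had been seen, and the other 2 window tests before, though the ratios over the vector were known by then.

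Over the vector sequence next to the PRE the ratios of the 2 antibodies pointed in opposite directions, with E(Z) at a log2 reverse over forward ratio of 0.56 and H3K27me3 at -0.32, whose own interval (-0.69 to 0.06) includes 0. The difference of the 2 ratios was 0.88 (0.53 to 1.22, counting error only), in which the input libraries cancel, and with 1 library per group it was not tested against replicates. In the part of the vector farther from the PRE the log2 ratios were 0.28 (-0.22 to 0.78) for E(Z) and -0.16 (-0.69 to 0.37) for H3K27me3. Both of these intervals include 0. Neither mark alone stands out from every reference: among windows of the vector's length thinned to its depth, an E(Z) ratio as high was found in 0.9% of 1000 windows outside domains and regions but in 9.33% of 525 windows inside H3K27me3 domains, and an H3K27me3 ratio as low in 1.14% of those inside but in 10.3% of those outside. A candidate explanation is the orientation of the PRE. The end that faces the vector in the reverse line is the low-coordinate end of the endogenous copy. Beyond that end, in the genome and with the lines summed, E(Z) IP over input was 1.48 (1.16 to 1.89) times that beyond the other end. H3K27me3 was 0.715 (0.570 to 0.896) times. In the 1 kb on each side of the endogenous fragment, orientation is the same in both lines. The log2 ratio there was 0.72 (0.38 to 1.06) for E(Z) and 0.01 (-0.32 to 0.34) for H3K27me3. Higher E(Z) next to a PRE, and an E(Z) ratio above that of H3K27me3, were thus also found without a change of orientation. A difference of the 2 ratios above 0 is therefore not particular to the vector. Whether it is larger over the vector was not tested. H3K27me3 in those flanks did not differ beyond counting error. An effect of the strand of the overexpressed RNA on the vector stays open and untested, because strand and orientation of the transgenic PRE change together.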

How the results depend on the processing

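The alternatives at a ratio of 1.5, inside and outside domains, and for vector bins without dm3 reads were chosen after the data were seen. Of 84 alternative values, 50 stayed within the counting interval of the reported value, 33 moved and 1 reversed. The rho has no interval, and both of its alternatives are counted as moved. With 1 read per position and strand, H3K27me3 enrichment was 2.02 (forward) and 2.29 (reverse) and the rho of both changes 0.059. At a calling ratio of 3, with 1 domain and 1 E(Z) region, H3K27me3 had 3.06, 3.75 and a log2 reverse over forward ratio of 0.29, and E(Z) 2.19, 4.49 and 1.04. That E(Z) region was the one at the vg PRE, where reads of the transgenic copy are included. At 1.5, with 337 domains and 898 regions, the values were 1.71, 1.90 and 0.15 for H3K27me3 and 1.53, 1.90 and 0.23 for E(Z). Regions called on the forward line alone (121 and 21) gave 2.11, 2.33 and 0.14, and for E(Z) 1.99, 2.09 and -0.39, the only reversal. Those called on the reverse line alone (216 and 271) gave 1.91, 2.21 and 0.22, and for E(Z) 1.45, 2.40 and 0.71. Each choice favours, by construction, bins high in the line used. Without input the H3K27me3 log2 ratio was 0.12 and the rho 0.044. Thinning to the shallowest library gave 0.47 for E(Z), and doubling the bins gave 2.08 and 2.36 for H3K27me3. The E(Z) log2 ratio was 0.69 inside and 0.12 outside H3K27me3 domains called at 1.5. Apart from the choice of regions, the cause of these moves was not tested. Region numbers also changed by over 1.5 times with 1 read per position (25 E(Z) regions), doubled bins (106 E(Z) regions) and domains of at least 10 kb (66).

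At vg the E(Z) log2 ratio ran from 0.72 to 1.04 and that of the H3K27me3 domain from 0.12 to 0.24 over the alternatives run. The E(Z) ratio relative to the median region ran from 0.10 (-0.24 to 0.44), without the PRE fragment, to 0.55. No domain at the PRE was called at 3. Alternatives for the gene lists were not run. No paired analysis was possible because there was 1 library per group.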

Other observations

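Counting 1 read per position and strand and calling regions on the forward line alone were decided on before the data were seen. The other tests reported here were chosen after the results they bear on had been seen.

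On several sequences outside the arms IP over input was lower in the reverse line. IP over input on the unplaced sequence Uextra was 1.02 in the forward line and 0.669 in the reverse line for E(Z), and 0.939 and 0.708 for H3K27me3. On the mitochondrial sequence M, H3K27me3 was 0.242 and 0.128 and E(Z) 0.256 and 0.206, but there the input changed: its share of reads on M was 0.479% in the forward line and 0.972% in the reverse line, while that of E(Z) was 0.123% and 0.2% and that of H3K27me3 0.116% and 0.124%, so without input the direction turns. On YHet E(Z) was 1.14 and 0.885, while H3K27me3, at 1.07 and 1.05, did not differ beyond counting error (log2 ratio -0.03, -0.15 to 0.10).

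H3K27me3 in its domains and E(Z) in its regions were higher in the reverse line nearly throughout, and H3K27me3 was higher in 33 of the 40 E(Z) regions. Repeated reads are argued against as the cause for H3K27me3, whose median log2 ratio was 0.18 (0.1813) with 1 read per position and strand, and the choice of regions by E(Z) reads is argued against as the whole cause by higher E(Z) in 98.5% of H3K27me3 domains, which were called without E(Z), though how much that choice adds to the size stays open: the median there was 0.25 against 0.62 in the E(Z) regions, and -0.39 in those called on the forward line alone. A candidate explanation is a yield difference common to all regions, for which chi-square over its degrees of freedom was 1.01 with 1 factor on the H3K27me3 ratios and 1.45 with 1 factor, of 2.36, on the E(Z) excess over input in all 40 regions, near the upper end of the range under chance (0.607 to 1.49). The E(Z) factor, fitted with vg included, put vg at 3.52 in the reverse line against 3.95 measured. In the 32 regions inside H3K27me3 domains called at 1.5, a set chosen after the data were seen, chi-square was 1.24. With 1 factor on the E(Z) ratios it was 1.84 in all regions and 1.59 in the 32, above the ranges under chance. A yield difference cannot be told apart from an effect of the overexpressed RNA on all targets, because there was 1 library per line and antibody. Nor can either be told apart from any other difference between the 2 lines, their embryos or their chromatin. The samples held no line without overexpression, so which line changed cannot be told.

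E(Z) regions outside H3K27me3 domains called at 1.5 differed little between the lines. Thinly covered bins called as regions are a candidate explanation, since these 8 regions had a median of 75.5 input reads per kb over both lines, against a mean of 220.5 on the arms and a median of 267.7 in the 32 regions inside. Their H3K27me3 IP over input was not low, at medians of 2.10 and 2.39. It divides by the same input counts, so it cannot decide on this explanation. No biological explanation was tested.

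Input density at the E(Z) region of the vg PRE was 1.86 times that of its 5 kb flanks in the forward line and 1.80 times in the reverse line. The median over the other 31 regions inside H3K27me3 domains called at 1.5 was 1.23 and 1.27. The vg region ranked 1 in the forward line and 3 in the reverse line. It also takes input reads of the transgenic PRE copy, which align to the same place. How much of the higher density comes from that copy was not tested.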
